A study of Homo sapiens with 6 samples.

How the data were processed

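The samples were 6 RNA-seq libraries of sorted human tumour cells, 1 per population (ALDH+, CD44+/CD24- and bulk) from each of 2 triple-negative breast cancer PDXs, MC1 (replicate 1) and Vari068 (replicate 2). The deposited table holds FPKM per gene locus, which the authors made from aligned fragments; per the submitters' processing notes STAR 2.3.1 was used with build GRCh37. The labels' protocols and the series text differ on the rest: the sample protocol names 10 ng of RNA and the Nugen Ovation RNASeq V2 kit with Kapa library preparation, and the series text 500 ng, a NEBNext poly(A) kit, 150 bp paired reads, tophat2 2.0.13 and the mouse build mm10. Gene symbols and coordinates in the table are human, and the program that computed the FPKM, its annotation and its use of strand are not given in the sources used here. Values of overlapping genes, of genes on opposite strands of a locus and of near-identical copies are therefore uncertain.

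The table had 24772 loci. Loci outside chromosomes 1 to 22 and X were left out, as were X-inactivation transcripts. CD24 is listed at a Y-chromosome locus of this build and was for that reason left out of the genes to be named. For 237 symbols listed at more than 1 locus, the locus with the highest mean FPKM was kept, which left 23022 genes. Start positions in the table count from 0, tested against gene spans in RefSeq, and are given counted from 1. A gene was tested when it had at least 1 FPKM in at least 2 of the 6 libraries, which left 11052 genes, of which 97 span fewer than 200 bases and 547 are listed at 0 in at least 1 library. Relative depth was read from the most frequent ratio, between libraries, of values under 0.5 FPKM. Absolute depth was read from the most frequent step of 269 values of olfactory and taste receptor genes, which have short single-exon loci. Of these steps 43 stood for 1 fragment, and 71.1% of the values were within 0.1 of a whole number. PCR copies were not separable from molecules, so such fragment numbers cover counting error only.

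Differences were fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with population and PDX as terms in all 6 libraries, and with empirical Bayes moderation with a trend on mean expression. The 3 pairs of populations and Vari068 against MC1 were tested two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. PDX was a block because the labels give each PDX as the source of 3 libraries. The deviations of libraries of the same PDX from their population means correlated at 0.866, 0.872 and 0.828 across genes. The difference of populations within each PDX has 1 library on each side and was not tested, and neither was a difference of these differences between the PDXs.

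Gene lists were written down before the data were examined, as were the comparisons, the rule for naming genes and the alternatives, apart from 2 alternatives named below. Lists with at least 5 tested genes were compared with all other genes by camera, with a preset correlation of 0.01 between genes. They were also tested by camera with an estimated correlation and by fry, with adjustment over the 23 lists of each comparison. The lists were the gate genes, epithelial and luminal, basal and myoepithelial, mesenchymal and EMT, stem cell and developmental signalling, G2 and mitosis, S phase and DNA replication, replication-dependent histones, OXPHOS complex I, OXPHOS complexes II to V, TCA cycle, fatty acid oxidation, glycolysis, hypoxia targets, pentose phosphate pathway, glutathione and thioredoxin antioxidants, NRF2 targets, unfolded protein response, immediate early and dissociation stress, NF-kB cytokines and chemokines, interferon response, cytosolic ribosomal proteins, and fibroblast and pericyte markers. Mitochondrially encoded genes and leukocyte, endothelial, and erythroid and adipocyte markers had too few members and were not tested. For each PDX the median of a list was placed among the medians of 10000 random lists of the same size matched on mean expression.

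Genes were named by a rule. In each comparison it takes the 10 with the largest rise and the 10 with the largest fall past the threshold, in the same direction in both PDXs, with at least 5 FPKM in the higher group. Where fewer passed, genes with the largest smaller-of-2-PDXs log2 difference are given as values. The rule adds 2 to 4 members of each described list and always CD44, ALDH1A1, ALDH1A3, ALDH2, EPCAM, CDH1, VIM and MKI67, and it leaves out short RNAs, pseudogenes and Y-linked genes. The small nucleolar RNAs, MIR324, SLC34A2, UQCRHL and HNRNPD fall outside the rule and were chosen after their values were seen.

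The alternatives were an offset of 0.1 FPKM, no filter on low values, quantile normalization, no trend, no PDX term, the 4 libraries of the populations compared, no population term, a 1.5-fold limit, and leaving out each library in turn. Leaving out loci under 200 bases, and quantile normalization before camera and before adjustment over a list alone, were added after the data were seen. Such adjustment used the limma p-values, which test against no difference rather than against the median gene. Genes of 2 lists were also resampled 10000 times to compare their medians, likewise added later. So was the reading of each list over expressed members, those with a mean of at least 1 FPKM over the 2 libraries compared in a PDX and above 0 in each. It used log2 ratios without an offset and 10000 random lists of expressed genes at the same level. The model was tested on simulated values of all genes with 200 genes changed by 2-fold, 4-fold or 8-fold. It recovered 100% of the genes changed 4-fold in each comparison. Noise was drawn independently for each gene and library, so shifts shared by many genes of a library were not simulated. Random lists were also matched on transcript length and GC content from GENCODE 29, which were found for 10738 genes. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.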

Results

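RNA was sequenced from tumour cells of 2 triple-negative breast cancer patient-derived xenografts (PDXs), human tumours grown in mice, named MC1 and Vari068. Cells carrying the mouse surface protein H2Kd were excluded by flow cytometry, and 3 human populations were sorted from each tumour. The ALDH+ cells, labelled E, were sorted for aldehyde dehydrogenase, and the CD44+/CD24- cells, labelled M, for surface CD44 without CD24. Both are populations enriched for breast cancer stem cells, and the question was how each differs from the bulk cells, which were ALDH- and CD44-/CD24+. Each population was sequenced once per PDX, which gave 6 libraries, 2 per population and 3 per PDX. For differences between populations, the p-values rest on how far such differences disagreed between the 2 PDXs. For Vari068 against MC1, they rest on the spread between sorted populations of 1 tumour per PDX.

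Between 8579 genes (MC1 bulk) and 10174 genes (Vari068 ALDH+) reached 1 FPKM per library. The FPKM table gives no fragment totals, and depth was estimated from the whole-number steps of its low values. In MC1, 1 FPKM of a transcript of 1 kilobase stood for 30.6 fragments in bulk, 49.7 in ALDH+ and 37.4 in CD44+/CD24- cells. In Vari068 it stood for 26.4, 25.0 and 28.6 fragments. The RNA integrity numbers in the labels were 9.3 for ALDH+, 8.8 for CD44+/CD24- and 8.5 for bulk cells of MC1, and 8.5, 8 and 7.8 in Vari068, so the order of integrity was the order of the populations in both PDXs.

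The FPKM of the median gene differed between populations, and list and gene differences between populations below are given relative to that gene on the log2(FPKM + 1) scale. The median gene was 0.37 higher in ALDH+ than in bulk cells (0.40 in MC1, 0.34 in Vari068). It was 0.18 higher in CD44+/CD24- than in bulk cells (0.04 in MC1, 0.29 in Vari068) and 0.19 higher in ALDH+ than in CD44+/CD24- cells (0.33 in MC1, 0.03 in Vari068). On this scale fold changes of genes at low FPKM are understated, and a gene at 0 FPKM in both libraries lies below the median gene by the whole shift. Lists were therefore also read in each PDX from members with a mean of at least 1 FPKM there, called expressed below, as log2 ratios without an offset relative to the median of all such genes. That median was 0.57 higher in ALDH+ than in bulk cells of MC1 and 0.49 higher in Vari068.

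Messenger RNAs of the sorting markers differed between the tumours. ALDH1A3, an aldehyde dehydrogenase that makes retinoic acid, had its highest FPKM in the ALDH+ cells of both PDXs: 8.996 against 3.68 in bulk and 1.92 in CD44+/CD24- cells of MC1, and 3.90 against 0.478 and 0.926 in Vari068. ALDH1A1, the family member most often linked to this activity, was listed at 0 in the 3 MC1 libraries and at 9.32 FPKM in Vari068 ALDH+ cells, against 0.0685 in bulk and 0.178 in CD44+/CD24- cells. ALDH2, the mitochondrial acetaldehyde dehydrogenase, stood at 16.9 FPKM in Vari068 ALDH+ cells against 2.16 in bulk cells, and at 0.329 to 1.08 FPKM in MC1. CD44, the hyaluronan receptor, had 82.9 FPKM in Vari068 CD44+/CD24- cells against 38.2 in bulk and 47.0 in ALDH+ cells. In MC1 CD44 had 99.4 FPKM in CD44+/CD24-, 87.4 in bulk and 113 in ALDH+ cells. Loci assigned to the Y chromosome, which on this build include the listed CD24 locus, were not analysed here. EPCAM, an epithelial adhesion protein, and CDH1, the epithelial cadherin, were higher in ALDH+ than in bulk cells of both PDXs, and CDH1 went from 11.6 to 18.5 FPKM in MC1 and from 9.53 to 18.6 in Vari068. Relative to the median gene, EPCAM was 0.20 and CDH1 0.23 higher in MC1, and 0.80 and 0.56 higher in Vari068. Much of the rise in MC1 was thus the shift of the median gene. ALDH1A1 did not reach the expression filter and was not tested. For the other 5 genes (CD44, ALDH1A3, ALDH2, EPCAM and CDH1), no difference between populations passed the threshold in limma, with adjusted p of 0.186 for ALDH1A3, EPCAM and CDH1 in ALDH+ against bulk cells.

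**Figure D1:**
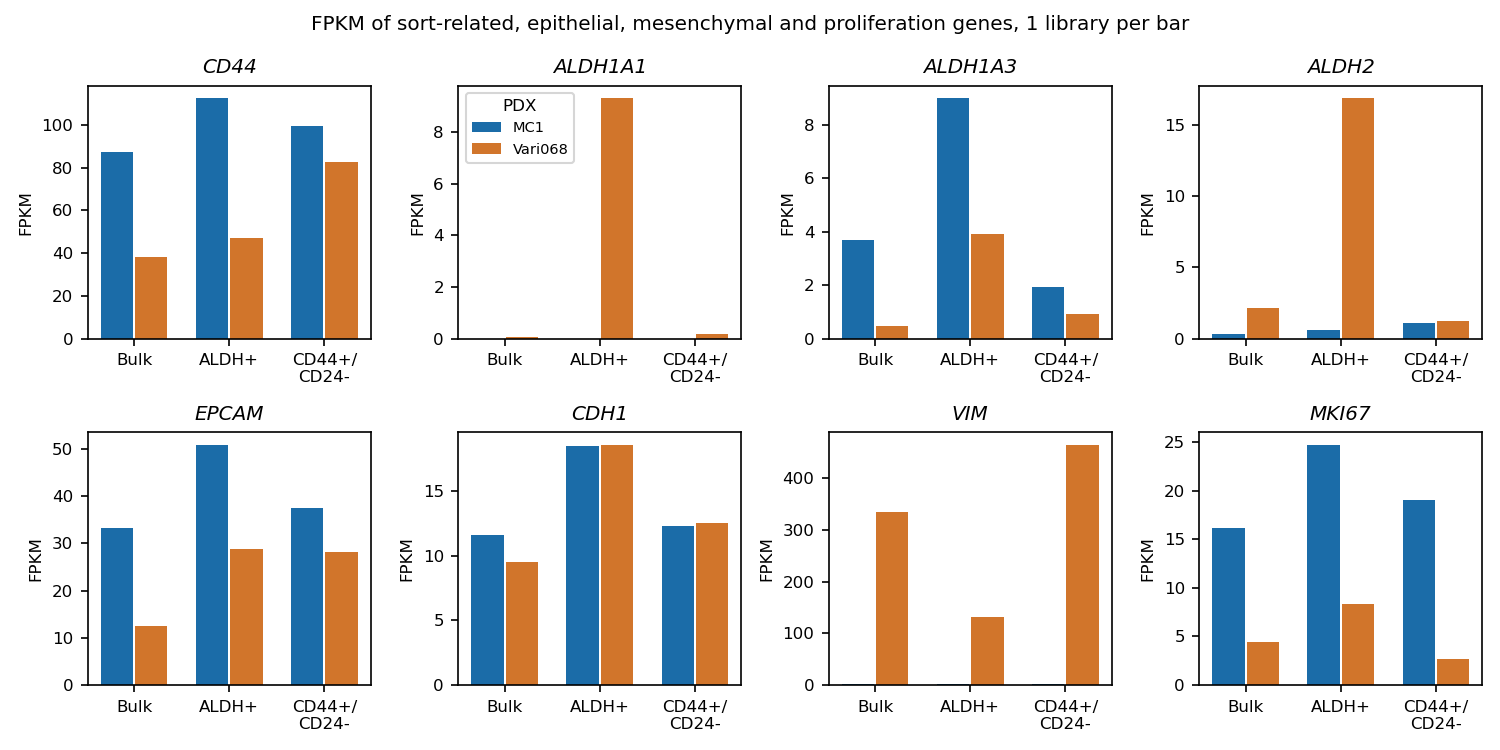
FPKM of CD44, ALDH1A1, ALDH1A3, ALDH2, EPCAM, CDH1, VIM and MKI67 in the 6 libraries, with 1 bar per library. The bars are grouped by population and coloured by PDX. ALDH1A3 was highest in the ALDH+ library of both PDXs, and VIM was at 1.01 to 1.34 FPKM in MC1 against 132 to 466 FPKM in Vari068.

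In ALDH+ cells of both tumours, genes of mitosis lay above the median gene relative to bulk cells, and mesenchymal genes expressed in each tumour lay below it. Genes of DNA replication and mitochondrial respiration also had medians above it, over expressed members nearer to those of random lists in MC1 than in Vari068. The median G2 and mitosis gene was 0.39 above the median gene (0.45 in MC1, 0.41 in Vari068), and 26 of 31 lay above it in both PDXs, against 28.75% of all genes tested. UBE2C, which loads ubiquitin for the anaphase-promoting complex, went from 28.6 to 56.7 FPKM in MC1 and from 19.9 to 45.3 FPKM in Vari068. CKS2, a cyclin-dependent kinase partner, went from 73.1 to 146 FPKM and from 47.7 to 95.5 FPKM. The cytokinesis gene ANLN and the chromosomal passenger BIRC5 were 0.78 and 0.68 above the median gene. Of the G2 and mitosis genes, 25 passed adjusted over the list alone and 0 over all genes (limma), with 26 at an unadjusted p under 0.05. These counts measure against no difference, while the median gene itself was 0.37 higher. After quantile normalization 0 of them passed adjusted over the list alone, with 6 at an unadjusted p under 0.05, and 0 genes of any other list did, with 0 to 6 per list at an unadjusted p under 0.05. The list's adjusted p was 7.66e-08 by camera with a preset correlation of 0.01 (adjusted p = 0.752 with an estimated correlation). S phase and DNA replication genes had a median of 0.24 (0.12 in MC1, 0.39 in Vari068), with 21 of 31 above in both PDXs and 15 past the threshold adjusted over the list alone. Over expressed members it was 0.09 in MC1 and 0.49 in Vari068, at percentile 93.3 and 100 among random lists of expressed genes. PCNA, the sliding clamp of DNA polymerase, went from 17.1 to 33.4 FPKM in MC1 and from 6.27 to 19.0 FPKM in Vari068, and the replication genes GINS2 and RRM2 were 0.96 and 0.78 above the median gene (camera adjusted p = 4.28e-06; adjusted p = 0.752 with an estimated correlation).

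Respiratory genes of the nuclear genome lay above the median gene in ALDH+ cells relative to bulk cells. Complex I genes had a median of 0.29 (0.20 in MC1, 0.36 in Vari068), with 29 of 38 above in both PDXs, and complexes II to V had a median of 0.25 (0.27 and 0.33), with 31 of 39 above in both. NDUFA4, a subunit of the electron transport chain, went from 6.79 to 15.4 FPKM in MC1 and from 6.91 to 12.1 FPKM in Vari068. UQCRFS1, the iron-sulphur protein of complex III, went from 15.3 to 30.9 FPKM and from 8.50 to 17.4 FPKM, and the ATP synthase gene ATP5O from 23.5 to 42.5 FPKM and from 31.9 to 71.7 FPKM. TCA cycle genes had a median of 0.24 (0.20 and 0.24), with 15 of 22 above in both PDXs and 1 past the threshold adjusted over the list alone. IDH2, the mitochondrial NADP-dependent isocitrate dehydrogenase, went from 6.15 to 12.5 FPKM in MC1 and from 5.83 to 15.1 FPKM in Vari068. By camera the adjusted p was 0.000315 for complex I, 0.000426 for complexes II to V and 0.00215 for the TCA cycle (adjusted p = 0.765 with an estimated correlation for each of the 3). Among 10000 random lists matched on expression, the median of complex I genes lay at the 76.7th percentile in MC1 and the 99.8th in Vari068. Over expressed members the complex I median was 0.06 in MC1 (percentile 79.7) and 0.25 in Vari068 (percentile 99.9), with 23 of 38 above in both. Complexes II to V had 0.12 (percentile 97.2) and 0.205 (percentile 99.5), with 26 of 38 above in both. The TCA cycle had 0.10 (percentile 92.6) and 0.23 (percentile 97.25), with 13 of 21 above in both.

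Epithelial, antioxidant and pentose phosphate genes also had positive medians in ALDH+ against bulk cells. Epithelial and luminal genes had a median of 0.32 (0.15 in MC1, 0.56 in Vari068), with 16 of 29 above in both PDXs and 1 past the threshold adjusted over the list alone. Among random lists matched on expression it lay at percentile 74.9 in MC1 and 100 in Vari068. Over expressed members the median was 0.03 in MC1 (percentile 58.1) and 0.57 in Vari068 (percentile 100). The tight-junction genes CLDN3 and CLDN7 were 0.74 and 0.77 above the median gene, while the keratin KRT8 was above it in Vari068 (1.55) and below it in MC1 (-0.16). The luminal regulator ELF5 was 2.74 above it in Vari068 and was under 0.1 FPKM in ALDH+ and bulk cells of MC1. Glutathione and thioredoxin antioxidants had a median of 0.25, with 25 of 34 above in both PDXs, among them MGST1 and TXNRD2 at 0.49 and 0.50. The pentose phosphate pathway, which makes NADPH and ribose, had a median of 0.16, with 5 of 9 above in both PDXs and 3 past the threshold adjusted over the list alone. PGD and RPIA were 0.73 and 0.60 above the median gene. For the 3 lists camera gave an adjusted p of 0.00215, 0.0298 and 0.0432 (adjusted p = 0.765, 0.876 and 0.765 with an estimated correlation).

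Mesenchymal genes had a median of -0.32 in ALDH+ against bulk cells (-0.18 in MC1, -0.47 in Vari068). In MC1 this takes in genes near 0 FPKM, whose values follow from the subtraction. Over expressed members the median was -0.22 in MC1 (16 genes, percentile 0.21) and -0.58 in Vari068 (18 genes, percentile 0.01), and 7 of the 12 expressed in both lay below the median gene in both. SNAI2, a transcription factor of the epithelial-mesenchymal transition, went from 2.02 to 1.32 FPKM in MC1 and from 52.0 to 23.7 FPKM in Vari068. The intermediate filament gene VIM went from 336 to 132 FPKM in Vari068 and stood at 1.01 and 1.34 FPKM in MC1. Fibroblast and pericyte markers had a median of -0.34 in Vari068 (-0.49 over its 8 expressed members, percentile 1.23). In MC1 3 of the 8 were expressed, so the median there is not read. In Vari068 the proteoglycan gene CSPG4 went from 7.74 to 1.65 FPKM and the matrix protein gene MGP from 118 to 50.95 FPKM, and the collagen gene COL1A1 was below the median gene in MC1 (-0.73) and above it in Vari068 (1.68). Immediate early and dissociation stress genes had a median of -0.16 (-0.14 and -0.21). Among them KLF2 was at -0.17 in MC1 and -1.90 in Vari068, and GADD45B at -0.42 and -0.50. Basal and myoepithelial genes had a median of -0.25 (-0.14 in MC1, -0.25 in Vari068) and a mean of -0.07. Over expressed members the basal median was -0.30 in MC1 (percentile 0) and -0.32 in Vari068 (percentile 0.92). Single basal genes differed between the PDXs, with the caveolin CAV1 at 0.23 in MC1 and -2.43 in Vari068 and S100A2 at -0.06 and 2.27. Camera gave an adjusted p of 8.24e-08 for mesenchymal genes, 0.0103 for fibroblast markers, 0.00215 for immediate early genes and 0.0291 for basal genes (adjusted p = 0.752 with an estimated correlation for each of the 4). After quantile normalization the adjusted p was 0.0795 for basal and myoepithelial genes and 0.139 for fibroblast and pericyte markers.

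Camera passed 12 of the 23 lists, 8 with higher and 4 with lower genes in ALDH+ cells. The same test with an estimated correlation passed 0, with 0 at an unadjusted p under 0.05. fry, which asks whether a list's genes move on balance in the same direction, passed 0, with 9 at an unadjusted p under 0.05. It does not compare a list with other genes, and its direction was higher for the 4 lists that lay below the median gene. The lists that did not pass included cytosolic ribosomal proteins (median 0.23, adjusted p = 0.214), fatty acid oxidation (0.19, adjusted p = 0.101), NF-kB cytokines and chemokines (0.18, adjusted p = 0.497) and replication-dependent histones (0.17, adjusted p = 0.766). Glycolysis had a median of 0.11 (adjusted p = 0.717), NRF2 targets 0.10 (adjusted p = 0.214), the gate genes 0.05 (adjusted p = 0.276) and the interferon response 0.03 (adjusted p = 0.953). The unfolded protein response had a median of 0.03 (adjusted p = 0.901), hypoxia targets 0.02 (adjusted p = 0.176) and stem cell and developmental signalling genes -0.00 (adjusted p = 0.598). The gate genes had 1 and NF-kB genes 2 members past the threshold adjusted over the list alone. The NF-kB median was 0.21 in MC1 and -0.04 in Vari068 over all tested members. Over expressed members it was 0.26 in MC1 (23 genes, percentile 99.99) and 0.40 in Vari068 (12 genes, percentile 98.8).

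Single genes outside the short RNAs did not pass in ALDH+ against bulk cells, and the largest differences shared by both PDXs are given as values. GABRP, a GABA receptor subunit made by basal-like breast tumours, went from 3.98 to 18.0 FPKM in MC1 and from 17.2 to 40.9 FPKM in Vari068, a log2 difference of 1.57 ± 0.30 (SE) before and 1.20 after subtraction of the median gene. PYCARD, the inflammasome adaptor, went from 1.47 to 4.59 FPKM and from 2.45 to 9.17 FPKM. TANK, a regulator of TRAF signalling, went from 3.46 to 8.55 FPKM and from 2.35 to 5.98 FPKM. The antimicrobial S100A7, the PDZ-domain partner PDZK1IP1, the nicotinic receptor modulator LYNX1, the secretory pathway gene ERGIC2 and DPCD were 0.68 to 1.05 above the median gene. Lower values were seen for S100A3 (-1.54), the interferon-induced IFITM2 (-1.21), the collagen IX gene COL9A3 (-1.05), the stress gene GADD45G (-0.77), TP53I3 (-0.61) and the metallothionein MT1F (-0.59). These values include the subtraction of the median gene, before which TP53I3 and MT1F were at -0.25 and -0.22. In MC1 bulk and ALDH+ cells IFITM2 was at 0.268 and 0.13 FPKM, GADD45G at 0.744 and 0.44 and COL9A3 at 3.6 and 3.195. MKI67, the proliferation marker, went from 16.2 to 24.8 FPKM in MC1 and from 4.39 to 8.38 FPKM in Vari068, which was 0.19 and 0.46 above the median gene.

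The genes that passed in ALDH+ against bulk cells were 3 small nucleolar RNAs, which guide chemical modification of ribosomal RNA and are encoded inside other genes. They were chosen for naming after their values were seen. FPKM of loci this short depend on how fragment length was corrected for, which is not given in the sources used here, and can be extreme: MIR324 was at 446615 FPKM in Vari068 bulk cells. SNORA15 lies in CCT6A (GRCh37, chromosome 7, 56128163 to 56128295). It was listed at 0 in both bulk libraries and at 5.21 and 12.9 FPKM in ALDH+ cells of MC1 and Vari068 (limma adjusted p = 0.0355). SNORA84 lies in IARS and overlaps MIR3651 (chromosome 9, 95054743 to 95054875), and it was listed at 0 in bulk cells and at 10.42 and 29.01 FPKM in ALDH+ cells (adjusted p = 0.0194). SNORD15A lies in RPS3 (chromosome 11, 75111435 to 75111582), and it had 8.10 and 5.04 FPKM in bulk cells and was listed at 0 in the other 4 libraries (adjusted p = 0.0194). An exact 0 in this table can stand for a failed estimate, since HNRNPD was listed at 0 in MC1 bulk cells and at 15.8 to 50.6 FPKM in the other 5 libraries. At an unadjusted p under 0.05 there were 2816 genes. Without loci under 200 bases limma called 0 genes, with 3005 at an unadjusted p under 0.05 and a smallest adjusted p of 0.186, for SLC34A2. Before subtraction of the median gene, 19 genes were higher and 7 lower by at least 1 on the log2(FPKM + 1) scale in both PDXs. In opposite directions 15 genes differed that far. This limit is stricter than 2-fold in FPKM, most of all at low values. Without loci under 200 bases these were 12 higher and 0 lower, against 2. The differences of the 2 PDXs correlated at r = 0.14 (Spearman 0.22) across genes, which are not independent replicates.

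Leaving out a library changed the count of 3 genes in ALDH+ against bulk cells to 20 without MC1 bulk, 825 without MC1 ALDH+, 8 without Vari068 bulk and 178 without Vari068 ALDH+, and quantile normalization gave 0 genes with 418 at an unadjusted p under 0.05. On simulated data of 11052 genes with 67 changed 2-fold, the same model recovered 55.2% and also called 24 unchanged genes, 15 of them under 200 bases.

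In CD44+/CD24- cells of both tumours, immediate early genes, which respond within minutes to growth factors and stress, lay below the median gene relative to bulk cells. Cytokine genes lay below it in MC1, while S100A7 and the asparagine synthetase gene ASNS had higher FPKM than in bulk cells. The median immediate early gene was at -0.35 (-0.17 in MC1, -0.54 in Vari068), and 16 of 28 lay below the median gene in both PDXs, against 25.6% of all genes. BTG2, an antiproliferative gene, went from 26.7 to 21.6 FPKM in MC1 and from 122 to 67.7 FPKM in Vari068. DUSP1, the phosphatase that switches off MAP kinases, went from 201 to 150.5 FPKM and from 90.1 to 64.1 FPKM. The mRNA-decay factor ZFP36 and the AP-1 subunit FOSB were at -0.59 and -0.57 (camera adjusted p = 9.92e-11; adjusted p = 0.447 with an estimated correlation). NF-kB cytokines and chemokines had a median of -0.18 (-0.28 and -0.15), with the chemokine CXCL2 at -0.65 (camera adjusted p = 0.000581; adjusted p = 0.996 with an estimated correlation). Over expressed members the median was -0.43 in MC1 (23 genes) and 0.14 in Vari068 (12 genes, percentile 84.2), so a lower value in Vari068 was seen only with genes near 0 FPKM included. Stem cell and developmental signalling genes had a median of -0.22 (-0.05 and -0.18), with the Notch target HES1 at -0.83, the Hedgehog receptor PTCH1 at -0.62 and the laminin receptor subunit ITGA6 at 0.61 (camera adjusted p = 0.0203; adjusted p = 0.942 with an estimated correlation).

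In CD44+/CD24- against bulk cells, the medians of G2 and mitosis genes and of histones lay below the median gene in Vari068 and above it in MC1, and this difference between the PDXs was not tested. The median G2 and mitosis gene was at -0.23, from 0.10 in MC1 and -0.55 in Vari068, and 5 of 31 lay below the median gene in both PDXs. FOXM1, a transcription factor of mitotic genes, went from 9.98 to 9.02 FPKM in MC1 and from 1.46 to 0.736 FPKM in Vari068, and the mitotic kinesin KIF20A from 2.33 to 2.10 FPKM and from 1.37 to 0.613 FPKM. Replication-dependent histones had a median of -0.26, from 0.05 in MC1 and -0.55 in Vari068, with HIST1H2BG at -0.24 and -1.71. Camera's adjusted p was 3.32e-06 for G2 and mitosis and 1.12e-05 for histones (adjusted p = 0.942 with an estimated correlation for both). Basal and myoepithelial genes had a median of 0.14 (0.24 in MC1, 0.23 in Vari068), with 10 of 22 above in both PDXs, among them the hemidesmosome genes LAMA3 (0.92) and ITGB4 (0.79); camera's adjusted p was 0.0612.

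Camera passed 5 of the 23 lists in CD44+/CD24- against bulk cells, each lower, with 6 at an unadjusted p under 0.05. With an estimated correlation it passed 0, with 1 at an unadjusted p under 0.05, and fry passed 0, with 2 at an unadjusted p under 0.05. Mesenchymal genes had a median of -0.03 (adjusted p = 0.749), with SPARC, a matrix glycoprotein, at -1.19 and TGFBI, a TGF-beta-induced matrix protein, at 0.92. Cytosolic ribosomal proteins had a median of 0.15 and glycolysis of 0.17 (adjusted p = 0.154 for both), the epithelial and luminal genes of -0.09 (adjusted p = 0.154) and S phase and DNA replication of -0.09 (adjusted p = 0.189). The gate genes had an adjusted p of 0.165, the unfolded protein response 0.154, and the remaining lists 0.721 or more. In the 23 lists 0 genes passed limma adjusted over the list alone or over all genes, and 0 to 3 genes per list had an unadjusted p under 0.05.

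Among single genes given as values, S100A7, an antimicrobial calcium-binding protein, went from 20.2 FPKM in bulk to 42.2 in CD44+/CD24- cells of MC1 and from 1.38 to 7.03 FPKM in Vari068, a log2 difference of 1.39 ± 0.28 (SE) before and 1.22 after subtraction of the median gene. Asparagine synthetase, ASNS, went from 4.98 to 12.97 FPKM and from 2.37 to 4.85 FPKM, and the circadian repressor NR1D1 from 3.87 to 7.79 FPKM and from 2.23 to 6.01 FPKM. C10orf116, the ribosomal protein gene RPL9, TMEM208 and SNHG9 were 0.56 to 1.15 above the median gene. GABRP went from 3.98 to 1.23 FPKM in MC1 and from 17.2 to 9.48 FPKM in Vari068. MARCKSL1, an actin regulator, went from 24.7 to 10.8 FPKM and from 10.5 to 5.97 FPKM, and SAT1, which acetylates polyamines, from 287 to 165 FPKM and from 356 to 228 FPKM. The differentiation-related NDRG2, the TGF-beta repressor TGIF1 and the death-associated kinase DAPK1 were at -0.81, -0.68 and -0.72. The limma adjusted p of each of these genes was 0.824.

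The genes that passed in CD44+/CD24- against bulk cells were 4 small nucleolar RNAs, also named after their values were seen. SNORD83B lies in RPL3 (chromosome 22, 39709824 to 39709916) and was listed at 0 in bulk and ALDH+ cells of both PDXs and at 550.1 and 844.5 FPKM in CD44+/CD24- cells (limma adjusted p = 1.96e-05). SNORD88C lies in C19orf48 (chromosome 19, 51305582 to 51305678) and showed the same pattern, at 226 and 354 FPKM (adjusted p = 2.42e-05). SNORA44 lies in SNHG12 (chromosome 1, 28906893 to 28907024) and was listed at 0 in bulk cells and at 20.7 and 94.0 FPKM in CD44+/CD24- cells (adjusted p = 0.0147). SNORD15A was listed at 0 in CD44+/CD24- cells and had 8.10 and 5.04 FPKM in bulk cells (adjusted p = 0.00951). At an unadjusted p under 0.05 there were 265 genes. Without loci under 200 bases limma called 0 genes, with 275 at an unadjusted p under 0.05. Before subtraction of the median gene, 8 genes were higher and 4 lower by at least 1 on the log2(FPKM + 1) scale in both PDXs. In opposite directions 12 genes differed that far. Without loci under 200 bases these were 1 higher and 1 lower, against 1. The differences of the 2 PDXs correlated at r = 0.08 (Spearman 0.03) across genes, which are not independent replicates.

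The count of 4 genes in CD44+/CD24- against bulk cells was 18, 96 and 20 without the MC1 bulk, ALDH+ or CD44+/CD24- library and 11, 97 and 8 without the Vari068 bulk, ALDH+ or CD44+/CD24- library. On simulated data of 11052 genes with 67 changed 2-fold, the model recovered 52.2% and also called 22 unchanged genes, 10 of them under 200 bases.

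Set against each other, the ALDH+ cells had higher values of mitotic, replication and respiratory genes relative to the median gene in both tumours than the CD44+/CD24- cells, and lower values of mesenchymal genes among those expressed in each tumour. Epithelial genes also had medians above the median gene in both. The median G2 and mitosis gene was 0.66 above the median gene (0.34 in MC1, 0.90 in Vari068), and 30 of 31 lay above it in both PDXs, against 26.4% of all genes. The largest were ANLN, BIRC5, the cyclin CCNA2 and the topoisomerase TOP2A at 1.04, 0.94, 0.87 and 0.81, and 27 of 31 passed adjusted over the list alone (camera adjusted p = 6.82e-17; adjusted p = 0.601 with an estimated correlation). Over all genes 0 of the 31 passed in limma, with 27 at an unadjusted p under 0.05. After quantile normalization 0 passed adjusted over the list alone, with 13 at an unadjusted p under 0.05. In the other lists 10 genes then passed this way, 5 basal and myoepithelial, 2 NF-kB, 1 epithelial, 1 gate and 1 TCA cycle gene. S phase and DNA replication genes had a median of 0.34 (0.20 and 0.54), with 24 of 31 above in both PDXs. RRM2, a subunit of ribonucleotide reductase, went from 12.7 FPKM in CD44+/CD24- to 26.5 in ALDH+ cells of MC1 and from 2.16 to 9.13 FPKM in Vari068 (camera adjusted p = 2.06e-09; adjusted p = 0.601 with an estimated correlation). Replication-dependent histones had a median of 0.33, from -0.18 in MC1 and 0.94 in Vari068 (camera adjusted p = 0.00808; adjusted p = 0.658 with an estimated correlation).

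Epithelial and luminal genes had a median of 0.34 in ALDH+ against CD44+/CD24- cells (0.21 in MC1, 0.51 in Vari068), with 18 of 29 above in both PDXs and 2 past the threshold adjusted over the list alone. The median lay at percentile 85.6 in MC1 and 100 in Vari068 among random lists matched on expression, and at 99.3 and 100 over expressed members. CLDN3, a tight-junction claudin, went from 13.9 to 31.5 FPKM in MC1 and from 0.333 to 2.42 FPKM in Vari068, and the mucin MUC1 and the keratin KRT19 were 1.05 and 0.93 above the median gene. Mesenchymal genes had a median of -0.46 (-0.19 and -0.52), with SNAI2 at -0.94. Over expressed members it was -0.19 in MC1 (17 genes, percentile 1) and -0.57 in Vari068 (19 genes, percentile 0.01), and 8 of the 14 expressed in both lay below the median gene in both. VIM went from 466 to 132 FPKM in Vari068, and the fibronectin gene FN1 was at -0.03 in MC1 and -2.20 in Vari068. Basal and myoepithelial genes had a median of -0.35 (-0.43 and -0.12), with LAMA3 at -1.36, ITGB4 at -1.15 and ITGA6 at -1.07. Over expressed members the basal median was -0.59 in MC1 (percentile 0) and -0.57 in Vari068 (percentile 0.02). Fibroblast and pericyte markers had a median of -0.33 in Vari068 (-0.26 over expressed members, percentile 11.2), and 3 of the 8 were expressed in MC1. Camera's adjusted p was 5.46e-05 for epithelial, 2.39e-06 for mesenchymal, 0.000175 for basal and 0.0466 for fibroblast genes (adjusted p = 0.642 for epithelial and 0.601 for the other 3 with an estimated correlation). After quantile normalization the adjusted p was 0.342 for fibroblast and pericyte markers and 0.0512 for glutathione and thioredoxin antioxidants.

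Complex I genes had a median of 0.27 in ALDH+ against CD44+/CD24- cells (0.32 in MC1, 0.30 in Vari068), complexes II to V of 0.26 (0.32 and 0.16) and TCA cycle genes of 0.22 (0.32 and 0.23). In both PDXs 29 of 38, 29 of 39 and 14 of 22 genes lay above the median gene, and NDUFA9, the ATP synthase gene ATP5A1 and IDH2 were at 0.54, 0.55 and 1.25. Among random lists matched on expression complex I lay at percentile 98.3 in MC1 and 99.9 in Vari068 and the TCA cycle at 99.9 and 98.0, while complexes II to V, at 94.1 and 96.4, lay inside the central 95%. By camera the adjusted p was 0.000314, 0.000795 and 0.000646 (adjusted p = 0.658, 0.658 and 0.642 with an estimated correlation), and 1 TCA cycle gene passed adjusted over the list alone. NF-kB cytokines and chemokines had a median of 0.43 (0.69 in MC1, 0.04 in Vari068) with 3 past the threshold adjusted over the list alone. Over expressed members the NF-kB median was 0.78 in MC1 (23 genes, percentile 100) and 0.38 in Vari068 (13 genes, percentile 97.6). CCL20, which attracts CCR6-bearing cells, went from 0.820 to 4.04 FPKM in MC1 and was listed at 0 and 1.04 FPKM in Vari068, and CXCL2, a neutrophil attractant, from 26.7 to 72.7 FPKM and from 1.51 to 3.80 FPKM. The pentose phosphate pathway had a median of 0.34 (0.38 in MC1, 0.14 in Vari068) and antioxidants of 0.19 (0.28 and 0.06). Among random lists matched on expression they lay at percentile 99.5 and 97.9 in MC1. In Vari068 they lay at 77.0 and 75.3, inside the central 95%. Camera's adjusted p was 0.0029 for NF-kB, 0.0287 for the pentose phosphate pathway and 0.0466 for antioxidants (adjusted p = 0.658, 0.658 and 0.799 with an estimated correlation). Camera passed 13 of the 23 lists, 10 higher and 3 lower in ALDH+ cells, with 15 at an unadjusted p under 0.05. With an estimated correlation it passed 0, with 0 at an unadjusted p under 0.05, and fry passed 0, with 5 at an unadjusted p under 0.05. The adjusted p was 0.0505 for the gate genes, which had 2 members past the threshold adjusted over the list alone, 0.0624 for glycolysis, 0.129 for hypoxia targets and 0.149 for immediate early genes, and higher for the other 6.

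**Figure D2:**
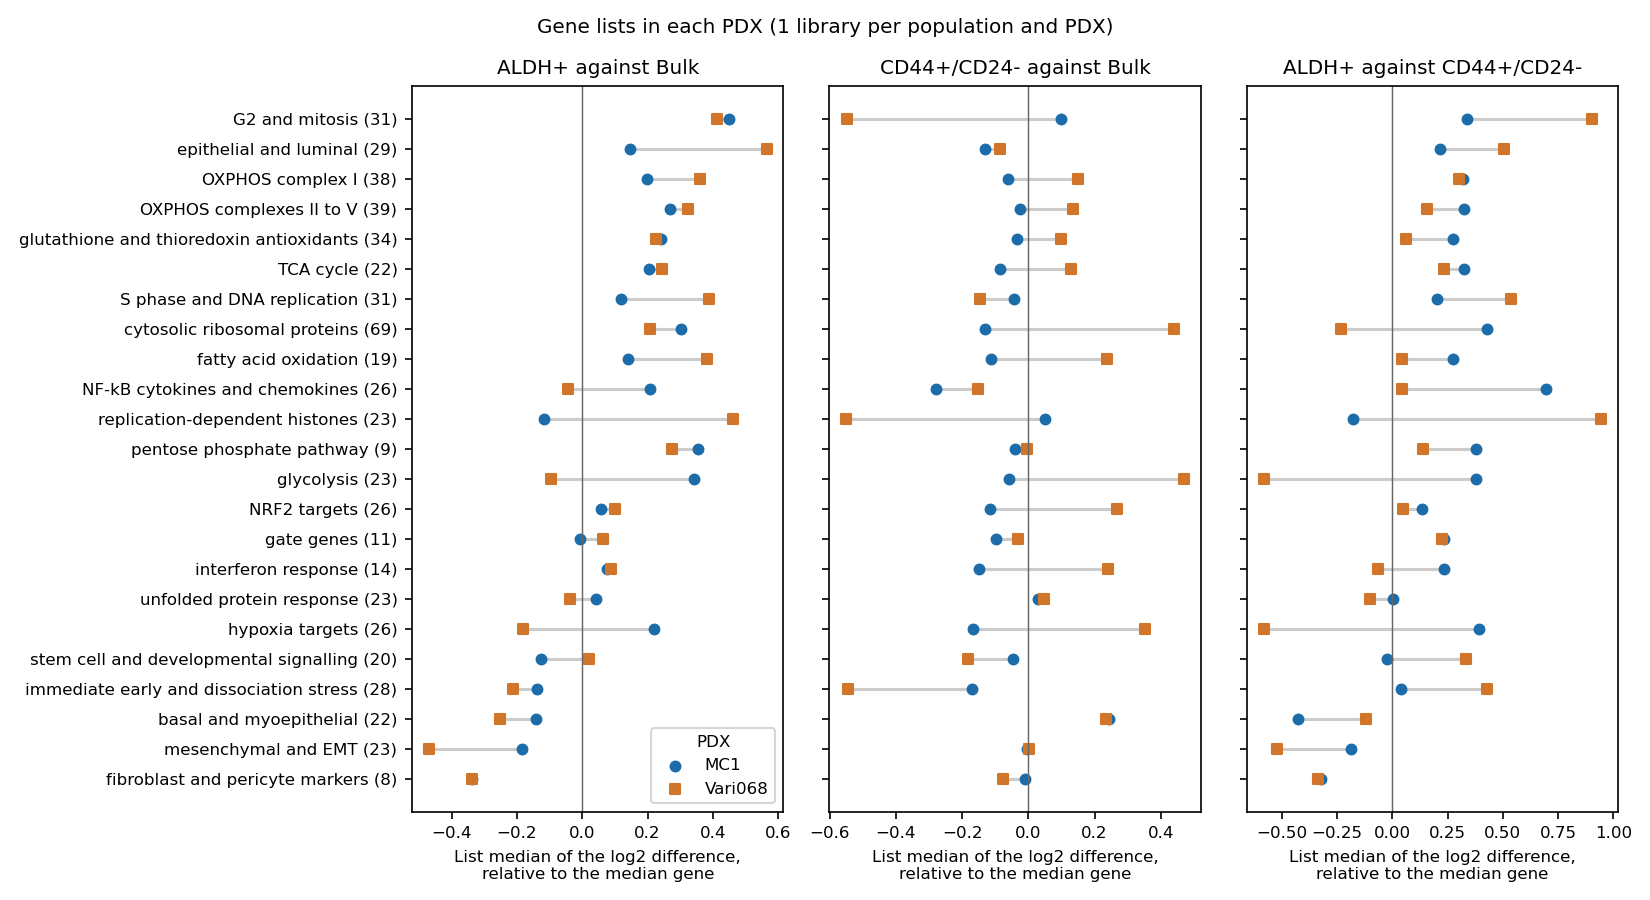
Median log2 difference of each gene list relative to the median gene, on the log2(FPKM + 1) scale, in MC1 and in Vari068 for each of the 3 comparisons between populations. G2 and mitosis genes sat at 0.45 and 0.41 in ALDH+ against bulk cells, and at 0.10 and -0.55 in CD44+/CD24- against bulk cells.

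GABRP had the largest value among single genes of 200 bases or more ranked by the smaller of the 2 PDX differences between ALDH+ and CD44+/CD24- cells, at a log2 difference of 2.55 ± 0.30 (SE) before and 2.36 after subtraction of the median gene. It went from 1.23 to 18.0 FPKM in MC1 and from 9.48 to 40.9 FPKM in Vari068 (limma adjusted p = 0.157). CLIC3, a chloride channel protein that recycles integrins, went from 8.07 to 23.1 FPKM and from 4.54 to 18.9 FPKM. IDH2 went from 4.39 to 12.5 FPKM and from 4.53 to 15.1 FPKM, and VGLL1, a cofactor of TEAD transcription factors, from 7.43 to 20.1 FPKM and from 0.434 to 4.19 FPKM (adjusted p = 0.364 for each of the 3). ALDH1A3, PDZK1IP1, the aldehyde dehydrogenase ALDH3B2 and the mitochondrial ribosomal protein gene MRPL28 were 0.96 to 1.37 above the median gene. Lower values were seen for S100A3 (-1.86), the procollagen enhancer PCOLCE2 (-1.32), NR1D1 (-1.18), the collagen VI gene COL6A1 (-0.79), the tubulin TUBB2A (-0.69) and the actin-binding PDLIM7 (-0.63). The genes that passed were SNORD83B and SNORD88C, both listed at 0 in ALDH+ cells. At an unadjusted p under 0.05 there were 1182 genes, and without loci under 200 bases limma called 0, with 1282 at an unadjusted p under 0.05. Before subtraction of the median gene, 27 genes were higher and 3 lower by at least 1 on the log2(FPKM + 1) scale in both PDXs. In opposite directions 24 genes differed that far. Without loci under 200 bases these were 26 higher and 0 lower, against 12. The differences of the 2 PDXs correlated at r = 0.08 (Spearman 0.08) across genes, which are not independent replicates.

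The count of 2 genes in ALDH+ against CD44+/CD24- cells was 716 and 178 without the MC1 or Vari068 ALDH+ library, 17 and 7 without the MC1 or Vari068 CD44+/CD24- library, and 3 without either bulk library. On simulated data of 11052 genes with 67 changed 2-fold, the model recovered 62.7% and also called 12 unchanged genes, 3 of them under 200 bases.

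The 2 tumours differed from each other far more than the populations within them did. By camera with the preset correlation, interferon-response, ribosomal protein and fibroblast-marker genes were higher in Vari068, and cytokine, basal and cell-cycle genes among others were higher in MC1. With an estimated correlation camera passed 0 of the 23 lists, with 0 at an unadjusted p under 0.05, and the adjusted p of these lists was 0.774 to 0.935. With the populations as a term, limma called 6009 of 11052 genes, 3340 higher and 2669 lower in Vari068, and 6688 genes had an unadjusted p under 0.05. The sorted populations of each tumour stood in as replicates, so these p-values leave out the spread between tumours. The median gene was 0.08 higher in Vari068. Across genes the first principal component held 76.1% of the variance and separated the PDXs. BGN, the matrix proteoglycan biglycan, had 1361 to 2532 FPKM in Vari068 and 0.319 to 0.380 FPKM in MC1, a log2 difference of 10.51 ± 0.26 (SE; adjusted p = 1.21e-05). VIM was 6.97 ± 0.36 higher (adjusted p = 2.55e-05), and MGP, BAMBI, a decoy receptor of TGF-beta signalling, and CTGF, a matricellular target of YAP, were 5.82, 6.12 and 5.70 higher. The cartilage and melanoma gene MIA was 7.63 higher and SCRG1, a stromal adhesion gene, 7.40 higher. C2orf40, a candidate tumour suppressor, was listed at 0 in MC1 and at 197 FPKM in bulk, 38.8 in ALDH+ and 172 in CD44+/CD24- cells of Vari068. SCGB2A2, the breast secretoglobin mammaglobin, was listed at 0 in MC1 and at 12.3, 122 and 139 FPKM in Vari068. UQCRH, a complex III subunit, was 6.70 higher, although reads of the near-identical copy UQCRHL can count for either gene.

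Leaving out short RNAs, pseudogenes and clone-based or LOC names, the genes with the largest decrease in Vari068 relative to MC1 were CST6, a cystatin protease inhibitor, at -6.50 ± 0.24, and IL1RN, the interleukin 1 receptor antagonist, at -6.48 ± 0.26 (limma adjusted p = 1.57e-05 for both). The defensin DEFB1, the long noncoding RNA UCA1 and the mucin MUC16 were at -5.88, -5.81 and -5.77. KLK5, an epidermal protease, had 46.6, 63.7 and 52.1 FPKM in MC1 and was listed at 0 in Vari068. The neutrophil chemokines CXCL1 and IL8 were at -5.63 and -5.15, and the GTPase RRAD at -5.21. S100A2, a p63 target of basal cells, had 840.2 to 1061 FPKM in MC1 and 9.46 to 62.6 FPKM in Vari068. Of the marker genes, MKI67 was at -1.86 ± 0.24 on the log2 scale (adjusted p = 0.000774), ALDH1A3 was at -1.10 (adjusted p = 0.00522), CD44 at -0.89 (adjusted p = 0.0289) and EPCAM at -0.85 (adjusted p = 0.0228). ALDH2 was 1.61 higher (adjusted p = 0.0408), and CDH1 was at -0.08 (adjusted p = 0.744). The adjusted p of CD44, ALDH2 and EPCAM was 0.232, 0.062 and 0.245 without MC1 bulk and 0.235, 0.063 and 0.252 without Vari068 bulk, and that of CD44 was 0.125 and 0.138 without MC1 or Vari068 ALDH+.

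On GRCh37, among genes higher in Vari068, BGN lies on chromosome X from 152760347 to 152775004, MIA on chromosome 19 from 41281082 to 41283398, SCRG1 on chromosome 4 from 174309299 to 174320617 and VIM on chromosome 10 from 17270258 to 17279592. C2orf40 lies on chromosome 2 from 106682113 to 106694609, UQCRH on chromosome 1 from 46769380 to 46782447, BAMBI on chromosome 10 from 28966424 to 28971868 and SCGB2A2 on chromosome 11 from 62037630 to 62040628. MGP lies on chromosome 12 from 15034115 to 15038853 and CTGF on chromosome 6 from 132269317 to 132272518. Among genes lower in Vari068, CST6 lies on chromosome 11 from 65779462 to 65780976, IL1RN on chromosome 2 from 113875470 to 113891593, DEFB1 on chromosome 8 from 6728097 to 6735529 and UCA1 on chromosome 19 from 15939757 to 15946230. KLK5 lies on chromosome 19 from 51446559 to 51456344, MUC16 on chromosome 19 from 8959520 to 9092018, CXCL1 on chromosome 4 from 74735109 to 74736955 and RRAD on chromosome 16 from 66955582 to 66959439. IL8 lies on chromosome 4 from 74606223 to 74609433 and S100A2 on chromosome 1 from 153533585 to 153538306.

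**Figure D3:**
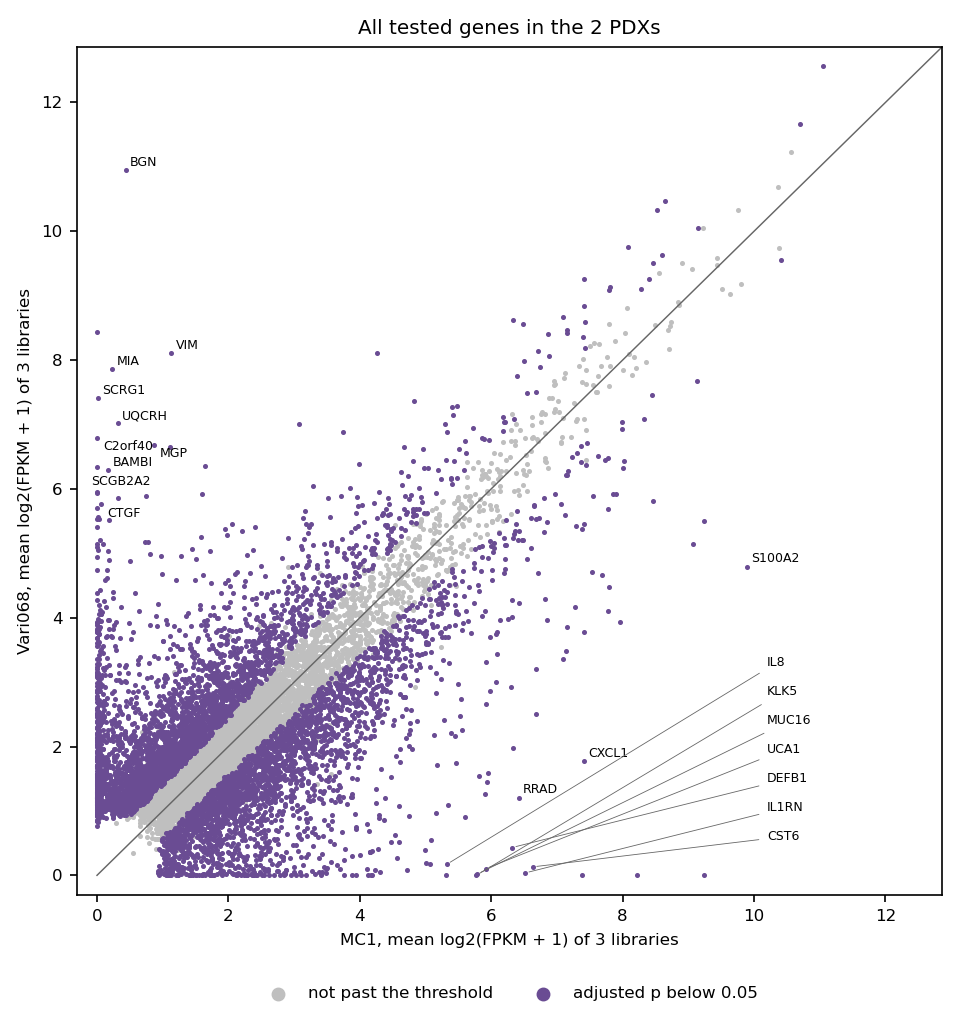
Mean log2(FPKM + 1) over the 3 populations of each of 11052 genes, with MC1 on the horizontal and Vari068 on the vertical axis and 20 named genes marked. BGN, at 10.51 above MC1, and CST6, at -6.50, lie far from the diagonal.

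Cell-cycle genes were lower in Vari068: the median G2 and mitosis gene was -1.33 from the median gene, 28 of 31 passed over all genes, all 28 lower, and 30 passed adjusted over the list alone (camera adjusted p = 5.45e-11; adjusted p = 0.774 with an estimated correlation). ANLN, the spindle protein TPX2 and FOXM1 were at -2.84, -2.56 and -2.26. S phase and DNA replication genes had a median of -0.60, with 17 of 31 past over all genes and 19 adjusted over the list alone, and replication-dependent histones of -1.07, with 14 of 23 past by either adjustment (camera adjusted p = 0.000969 and 0.000123; adjusted p = 0.774 with an estimated correlation for both). NF-kB cytokines and chemokines had a median of -1.62, with 24 of 26 past over all genes (4 higher, 20 lower) and 25 adjusted over the list alone (camera adjusted p = 1.89e-05; adjusted p = 0.774 with an estimated correlation). Basal and myoepithelial genes had a median of -1.96, with 19 of 22 past over all genes (5 higher, 14 lower) and 20 adjusted over the list alone; the keratin KRT6A was at -3.67 and the desmoglein DSG3 at 3.63. Epithelial and luminal genes had a median of -0.93, with 22 of 29 past by either adjustment (5 higher, 17 lower over all genes), and KRT18 at -3.66 and CLDN3 at -3.52. TCA cycle genes had a median of -0.76, with 12 of 22 past by either adjustment, all 12 lower. Camera's adjusted p was 0.00485 for basal, 0.00469 for epithelial and 0.00248 for TCA cycle genes (adjusted p = 0.774, 0.781 and 0.774 with an estimated correlation).

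Fibroblast and pericyte markers had a median of 1.86 in Vari068 against MC1, with 6 of 8 past by either adjustment (5 higher, 1 lower over all genes), and the collagen VI genes COL6A1 and COL6A2 at 5.54 and 4.94. Only these 8 of the 20 listed markers were tested, and of 30 listed interferon-response genes only 14. The interferon response had a median of 0.83, with 12 of 14 higher by either adjustment and IFI6 at 5.55. Cytosolic ribosomal proteins had a median of 0.52, with 23 of 69 past over all genes, all 23 higher, and 17 adjusted over the list alone. Camera's adjusted p was 0.0248, 0.000969 and 0.0102 for the 3 lists (adjusted p = 0.774, 0.774 and 0.935 with an estimated correlation). Mesenchymal genes had a median of 0.76, with 21 of 23 past over all genes (14 higher, 7 lower) and 21 adjusted over the list alone (camera adjusted p = 0.29), and VIM was among the higher and INHBA (-3.96) among the lower genes. The unfolded protein response had 17 of 23 genes past over all genes and 19 adjusted over the list alone (camera adjusted p = 0.07). Camera passed 10 of the 23 lists, 3 higher and 7 lower in Vari068, with 12 at an unadjusted p under 0.05. With an estimated correlation it passed 0, with 0 at an unadjusted p under 0.05, while fry passed 9, with 11 at an unadjusted p under 0.05. fry did not pass cytosolic ribosomal proteins (adjusted p = 0.268), histones (adjusted p = 0.107) or the TCA cycle (adjusted p = 0.0729), and it added stem cell genes and immediate early genes (adjusted p = 0.0361 for both).

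The count of 6009 genes between the PDXs was 3846 without the MC1 bulk and 3832 without the Vari068 bulk library, and quantile normalization gave 6425, 3193 higher and 3232 lower. On simulated data of 11052 genes with 67 changed 2-fold, the model recovered 89.6% and also called 13 unchanged genes, 7 of them under 200 bases.

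Markers of other cell types were looked up as 4 further lists. None of the 13 mitochondrially encoded protein genes was in the table. Of leukocyte markers 2 of 24 reached the expression filter, with CD68 highest at 3.72 FPKM, and of endothelial markers 2 of 15, with ENG highest at 4.09 FPKM. Of erythroid and adipocyte markers 0 of 14 reached it, with CD36 highest at 2.98 FPKM.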

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

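The test of transcript length or GC content was planned before its result was seen, but the pattern it weighs was picked from these data. In 13 cases, each 1 of 8 gene lists in 1 comparison, the medians of the 2 PDXs had opposite signs, and MC1 lay outside the central 95% of random lists matched on expression on 1 side and Vari068 on the other side, which is why they are given here. Over members with a mean of at least 1 FPKM in a PDX, as ratios without an offset, all 13 kept opposite signs and 10 still lay outside on both sides. The same libraries that picked the cases were reread, so this bears on the offset and low values only. Each PDX gives 1 library per population, so the difference between the PDXs was not tested. The 3 comparisons share libraries, so these values are not independent of each other.

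In ALDH+ against bulk cells, glycolysis genes had a median of 0.34 in MC1 and -0.09 in Vari068, a difference (MC1 minus Vari068) of 0.44. Hypoxia targets had 0.22 and -0.18, a difference of 0.40, and replication-dependent histones -0.12 and 0.46, a difference of -0.58.

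In CD44+/CD24- against bulk cells, the difference was 0.65 for G2 and mitosis genes (0.10 in MC1, -0.55 in Vari068) and -0.57 for cytosolic ribosomal proteins (-0.13 and 0.44). It was -0.52 for hypoxia targets (-0.17 and 0.35), -0.39 for the interferon response (-0.15 and 0.24), -0.38 for NRF2 targets (-0.12 and 0.27) and -0.35 for fatty acid oxidation (-0.11 and 0.24).

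In ALDH+ against CD44+/CD24- cells, the difference was 0.66 for cytosolic ribosomal proteins (0.43 in MC1, -0.23 in Vari068) and -1.12 for replication-dependent histones (-0.18 and 0.94). It was 0.96 for glycolysis (0.38 and -0.58) and 0.98 for hypoxia targets (0.39 and -0.58). ENO2, a glycolytic enolase, went from 8.35 FPKM in CD44+/CD24- to 11.5 in ALDH+ cells of MC1 and from 13.6 to 4.81 FPKM in Vari068. SLC2A1, the glucose transporter, went from 19.1 to 36.6 FPKM and from 41.5 to 21.2 FPKM, and VEGFA, the angiogenic growth factor, from 9.33 to 17.2 FPKM and from 182 to 93.8 FPKM.

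The opposite direction of glycolysis and hypoxia genes in ALDH+ against CD44+/CD24- cells was set against transcript length or GC content as the explanation. Among random lists matched on expression, length and GC content, the difference between the PDXs of the 47 genes lay at percentile 100, which argues against length and GC content as the whole cause. A difference between the tumours themselves stays open and was not tested. The time and handling of each sort also stay open, since the labels give no batch and each value rests on 1 library.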

How the results depend on the processing

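The alternatives without loci under 200 bases and with quantile normalization before list tests were chosen after the data were seen.

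In ALDH+ against bulk cells, 3 genes passed in limma. The count was 0 with no filter (2831 at an unadjusted p under 0.05), 0 after quantile normalization (418), 0 without the PDX block that pairs the libraries (121) and 0 without loci under 200 bases (3005). It was 2 to 4 with the other planned settings and 2 to 825 when 1 library was left out. In CD44+/CD24- against bulk cells, 4 passed, with 2 without a filter, 2 without the PDX block, 96 in the 4 libraries alone, 0 without loci under 200 bases (275 at an unadjusted p under 0.05) and 8 to 97 when 1 library was left out. In ALDH+ against CD44+/CD24- cells, 2 passed, with 0 without loci under 200 bases (1282 at an unadjusted p under 0.05) and 3 to 716 when 1 library was left out. The loss without short loci follows from the setting, since each called gene was a short RNA; the cause of the other changes was not tested. Leaving out a library leaves 1 sample in its group, which is assumed to vary like the others. Without either ALDH+ library some named genes passed in limma. In ALDH+ against bulk cells these were ALDH1A3, PYCARD, DPCD, LYNX1 and CLDN7, and in ALDH+ against CD44+/CD24- cells GABRP, CLIC3, ALDH1A3, IDH2, VGLL1, PDZK1IP1, ALDH3B2 and CCL20. In CD44+/CD24- against bulk cells they were S100A7, NR1D1, ASNS, C10orf116 and SPARC.

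Between Vari068 and MC1, 6009 genes passed, 5166 to 6425 under the other settings and 3832 to 5966 when 1 library was left out. Higher genes outnumbered lower ones as reported (3340 and 2669) and lower ones outnumbered higher ones after quantile normalization (3193 and 3232), without MC1 CD44+/CD24- (2559 and 2723) and without Vari068 CD44+/CD24- (2543 and 2743). Of the genes named above, CD44, ALDH2 and EPCAM did not pass without a filter or without a bulk library, CD44 also not without an ALDH+ library, ALDH2 not after quantile normalization and ALDH1A3 and EPCAM not without the population term; each kept its direction. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes, the real split with 6009, and the highest other gave 0; 10 splits are too few for a share under 0.05.

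In ALDH+ against bulk cells 26 genes (19 higher, 7 lower) differed in the same direction by at least 1 on the log2(FPKM + 1) scale. They became 164 with an offset of 0.1 and 16 after quantile normalization (6 higher, 10 lower). At a 1.5-fold limit on the reported scale they became 904, and without short loci 12 (12 higher, 0 lower). The 12 in CD44+/CD24- against bulk cells became 36, 14 (7 higher, 7 lower), 46 and 2 (1 higher, 1 lower), and the 30 in ALDH+ against CD44+/CD24- cells 127, 12 (6 higher, 6 lower), 329 and 26 (26 higher, 0 lower). Quantile normalization moved 88 of 112 named gene values by more than 1 SE in ALDH+ against bulk cells, 1 of 112 in CD44+/CD24- against bulk cells and 41 of 108 in ALDH+ against CD44+/CD24- cells. After it 0 G2 and mitosis genes passed adjusted over the list alone in either comparison of ALDH+ cells (6 and 13 at an unadjusted p under 0.05), against 25 and 27 as reported, and 5 basal and myoepithelial genes passed in ALDH+ against CD44+/CD24- cells, against 0 as reported (5 at an unadjusted p under 0.05). The cause was not tested.

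Camera with the preset correlation passed 12, 5 and 13 lists in these 3 comparisons and 10 between the PDXs. With an estimated correlation the counts were 0, 0, 0 and 0 (0, 1, 0 and 0 at an unadjusted p under 0.05). fry gave 0, 0, 0 and 9 (9, 2, 5 and 11 at an unadjusted p under 0.05). For 5 lists with lower genes by camera, fry's direction was higher. In ALDH+ against bulk cells these were basal and myoepithelial (median -0.25), fibroblast and pericyte (-0.32), immediate early (-0.16) and mesenchymal genes (-0.32), with fry adjusted p of 0.292, 0.531, 0.116 and 0.973. In CD44+/CD24- against bulk cells it was stem cell and developmental signalling (-0.22; fry adjusted p = 0.936). By construction fry measures against no difference, and camera against the other genes. After quantile normalization camera passed 13 (11 higher, 2 lower; 10 shared), 8 (3 higher, 5 lower; 5 shared), 14 (10 higher, 4 lower; 11 shared) and 12 (5 higher, 7 lower). The cause of the other changes between these tests was not tested. At 1 FPKM a transcript of 1 kilobase has 25.0 to 49.7 fragments, which limits differences of genes near the filter.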

Other observations

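The test of library depth and the resampling of genes were chosen only after results were seen, and the other tests below before. UQCRH had 0.0792 to 0.391 FPKM in MC1 and 92.2 to 161 FPKM in Vari068, and its copy UQCRHL 0.587 to 0.764 and 44.9 to 74.4 FPKM.

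FPKM of most genes were higher in ALDH+ than in bulk cells in both PDXs, with the median gene 0.40 higher in MC1 and 0.34 in Vari068. In Vari068 the median difference was 0.34 although the ALDH+ library had 0.94 times the depth of the bulk library. This argues against a difference in library depth as the cause there. In MC1 the ALDH+ library had 1.63 times the depth of the bulk library, so depth stays open there. The 50 genes with most fragments left a share to other genes that predicted -2.52% of the difference in MC1 and 47.6% in Vari068. In MC1 this argues against them as the whole cause. In Vari068 the share takes in short loci such as MIR324, at 446615 FPKM in bulk cells. FPKM of such loci depend on an unknown length correction, so the value there decides nothing and this explanation stays open. RNA integrity cannot be told apart from population, since it was highest in ALDH+ and lowest in bulk cells of both PDXs; the rank correlation of the difference with transcript length across genes was -0.0304 in Vari068 and -0.134 in MC1. FPKM times transcript length, summed over all genes kept, was 449.2 in ALDH+ against 301.7 in bulk cells of MC1, in relative units. In Vari068 it was 419.4 against 352.9, and this bulk total takes in the extreme value of MIR324. The FPKM of the libraries were thus not shares of the same gene total. In CD44+/CD24- cells the total was 305.1 in MC1, near bulk cells, and 425.8 in Vari068, near ALDH+ cells. The median expressed gene differed by 0.07 and 0.05 in these pairs. By contrast it was 0.57 and 0.49 higher in ALDH+ than in bulk cells of MC1 and Vari068. The shift thus went with the gene total. These totals sum the same FPKM and cannot show why they differ. How far the totals make up the shift was not tested. A difference between the populations themselves also stays open and was not tested.

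Oxidative phosphorylation and TCA cycle genes lay above the median gene in ALDH+ against bulk cells, with a median of 0.22 in MC1 and 0.35 in Vari068 over 95 genes. Against random lists matched on expression, length and GC content these medians lay at percentile 98.7 and 100, which argues against length and GC content as the whole cause. A higher FPKM of mitochondrial protein genes in general stays open in both PDXs. The median of 75 mitochondrial ribosomal protein genes was 0.17 in MC1 (percentile 74.4) and 0.28 in Vari068 (percentile 99.7). The respiratory median was 0.05 and 0.07 higher, and with genes resampled 10000 times 95% of these differences lay from -0.01 to 0.12 and from -0.02 to 0.20. RNA integrity, which follows the populations, and a difference between the populations themselves stay open for this pattern and were not tested.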
